A study of Homo sapiens with 6 samples.

How the data were processed

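Total RNA of KPL4 cells, 3 control and 3 ESR2 knockout samples, was extracted with a column kit and hybridised as biotin-labelled cDNA to Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of log2 signal values, which were made with RMA in Transcriptome Analysis Console, per the submitters' processing notes. Versions of these tools, the array's genome build and the summarisation settings were not given in the sources used here. RMA corrects background, normalizes between arrays and combines probes to 1 value per probe set, so differences shared by all genes of an array are removed. The log2 scale was inferred from the values, which run from about 2 to just under 20. No centring per gene was seen, and scanner files were not used here. A share of 0.567% of values lay above 16, beyond what a 16-bit scanner reading gives on a plain log2 scale, so folds are on the scale of the deposited values, which may be stretched at the top.

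Probe sets were named from the platform annotation, updated through Entrez ID with a RefSeq gene table (assembly GRCh38.p14). Of 134748 probe sets, 35528 had 1 gene symbol, 1119 several and 98101 none listed here. Probe sets with several symbols were named for no gene. Of the rows with 1 symbol, 24364 genes matched RefSeq, and all of these symbols were already current. For 1425 genes with several probe sets, the one with the highest mean over the 6 arrays was used, leaving 33578 genes, 17371 of them protein-coding. No filter on brightness was used in the main setting. "Bright" means a mean above the median of tested genes, 5.05. A fold is given as "at least" where the lower group mean was dim, below that median, since such a signal was not shown to lie above background. RefSeq served only for names, classes and gene order, since the array's build was not stated, and no coordinates are printed.

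Groups were compared with limma 3.58.1 in R 4.3.3 (data.table package, version 1.17.8), using lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 4 and the prior added 6.84. All 37 gene lists were written before the data were examined, as were the rule for named genes, the tests of genes and lists and most alternatives. Lists cover signalling, migration, stress, metabolism, cell cycle, immune genes and markers of other cell types, and 1283 of 1407 members (91.2%) were measured. They were tested with camera at a preset correlation of 0.01, for lists of at least 5 members. One of the lists and 1 of the receptors fixed for naming are not reported here. With an estimated correlation, 0 of 12 calls held. The estimate was below the preset 0.01 for cholesterol synthesis (-0.021), NF-kB (-0.012) and PI3K and FOXO genes (0.0020). Losing those calls therefore cannot be put down to a higher correlation among their own members. For histone genes the estimate was 0.019, near the preset, yet the adjusted p went from 9.3e-10 to 0.13. With an estimated correlation, camera also uses the residual degrees of freedom, 4 here, which makes small p-values hard to reach. A call lost in that setting is therefore not evidence that correlation among members produced it. Fry was also run. Its directional test asks whether a list's genes move on balance one way, its mixed test whether they change in either direction, and neither compares a list with other genes.

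Named genes were ESR2, SYNE2, receptors fixed beforehand, ELMO1 and GPR141, the 12 largest rises and 12 largest falls, up to 3 higher and 3 lower members per list, and ACTB, GAPDH and TBP. The largest changes were taken among called genes whose groups did not overlap and whose higher mean was bright, leaving out symbols of unnamed, small, immunoglobulin, T cell receptor and antisense genes and pseudogenes. Where a list had no called member, its largest change is a value only: ESAM differed by -0.42 (adjusted p = 0.056) among endothelial and RPL5 by -0.35 (adjusted p = 0.16) among ribosomal genes.

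Blocks were sought after the data were examined. Medians were taken over windows of 25 neighbouring bright protein-coding genes, and a window counted where its median, minus that of all ordered genes, exceeded 0.465, the largest value in 200 random gene orders. Runs of 1 sign within a window of each other were joined, and blocks had at least 10 genes. With windows of 15 and 41 genes, 6 and 7 of the 7 blocks were found again in part. Without joining of runs, windows of 15 passed at 247 of the 552 block genes. Windows of 41 passed at 513 of the 552 and at 873 genes in all, some of them on chromosomes 1 and 6, which hold no block. The extent of the blocks therefore rests on the chosen window and joining. To test them on genes that took no part, blocks were also sought in every second gene with windows of 13, and the genes in between were compared with 200 random draws. The largest window of each block was also set beside 1000 new random orders.

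The steps were tested on simulated data over 33578 genes with the measured means and spreads for the knockout against control comparison. Changes of 0.5 on the log2 scale were recovered for 2 of 67 genes, of 1 for 43 of 67 and of 2 for 66 of 66, and 3 of 33378 unchanged genes were called. So a change of 0.5 was mostly missed in this simulation. It held far fewer changed genes than the 2691 called in the data, which makes the adjusted threshold stricter. Its recovery at 0.5 therefore does not give the sensitivity of the real comparison. With no change, 0 of 37 lists were called, and a list shifted by 0.4 was called. Genes varied independently in this simulation, whereas the correlation estimated in the data was 0.235 for the NRF2 list. It therefore does not give the rate of false list calls in the data. Of 60 neighbouring genes shifted by 0.7 among 11780, 60 were found, with 2 genes outside. Alternatives covered normalization, brightness, the probe set rule, variance moderation, the replicate number as a block, leaving out each array, other tests and array weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.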

Results

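Gene expression was measured on 6 Affymetrix arrays of KPL4 cells, an established human inflammatory breast cancer line. Of these arrays, 3 came from control cells and 3 from cells in which ESR2, the gene for estrogen receptor beta (ERβ), had been knocked out with CRISPR/Cas9. The labels call the 3 arrays of each group biological replicates. They do not say whether these were separately grown cultures, whether the knockout cells were a clone or a pool, or what the control cells had received. The p-values therefore measure the spread between these 6 samples, which may be partly technical. The median log2 signal over all 134748 probe sets was 4.09, 4.11 and 4.09 on control arrays 1, 2 and 3, and 4.08, 4.08 and 4.09 on knockout arrays 1, 2 and 3. Over genes above the median brightness, Pearson's r across genes was 0.995 to 0.997 between arrays of a group and 0.986 to 0.988 between arrays of different groups. Genes are not independent replicates, so these coefficients only describe the arrays. The first principal component held 66.9% of the variance and set the 2 groups apart. The number of arrays, 3 per group, limits the precision of each value below.

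The targeted gene was examined first. ESR2 (probe set TC1400009402.hg.1) had a log2 signal of 3.95 ± 0.23 (SD, n = 3) in control and 3.997 ± 0.093 (SD, n = 3) in knockout cells. The difference of 0.05 (SE 0.15) was smaller than the spread between replicates (limma adjusted p = 0.90). Both means lay below the median brightness of the tested genes, 5.05. A frameshift need not lower a transcript, and probes outside the edited part check nothing, so the arrays could not check the label of either group. SYNE2, which neighbours ESR2, differed by 0.01 (SE 0.15, adjusted p = 0.98). None of the following 6 hormone and growth factor receptors, fixed for naming, passed the test. The log2 difference was 0.43 for ESR1, the gene for estrogen receptor alpha (adjusted p = 0.13), 0.11 for PGR, the progesterone receptor (adjusted p = 0.78), and 0.25 for GPER1, a membrane estrogen receptor (adjusted p = 0.57). It was 0.37 for ERBB2 (adjusted p = 0.11), 0.33 for ERBB3 (adjusted p = 0.15) and -0.21 for EGFR (adjusted p = 0.52), which code for receptor tyrosine kinases. ESR1 (3.92 in control and 4.36 in knockout cells), PGR (4.90 and 5.00) and GPER1 (4.19 and 4.44) were dim like ESR2. Their signal was therefore not shown to lie above background. Of the reference genes, ACTB was higher in knockout cells by 0.52 (SE 0.13, adjusted p = 0.037), a call lost without any 1 of the 6 arrays (adjusted p = 0.055 to 0.13) and lost after repeated quantile normalization (adjusted p = 0.082) or with a replicate block (adjusted p = 0.066). GAPDH differed by 0.15 (adjusted p = 0.58) and TBP by -0.11 (adjusted p = 0.74).

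The main comparison asked which transcripts differ when ESR2 is disrupted in these cells. The largest rise was that of CD36, a fatty acid transporter and scavenger receptor, from 6.91 ± 0.18 to 13.66 ± 0.02 (log2 signal, SD, n = 3), or 108-fold (adjusted p = 9.3e-10). GLYATL3, a glycine acyltransferase family member, rose 68.5-fold, TMEM47 37.7-fold and BPIFB1, a secreted airway epithelial protein, 23.9-fold. CLEC3A rose 13.6-fold, CYP4X1, a cytochrome P450, 12.5-fold, CATSPERB 11.6-fold and S100A9, a subunit of calprotectin, 10.7-fold. IL17RD, an antagonist of fibroblast growth factor signalling, rose 9.84-fold, TFPI2, a serine protease inhibitor, 9.61-fold and SLC6A14, an amino acid transporter, 8.74-fold. TSPAN7, a tetraspanin, fell the most, from 12.20 ± 0.03 to 7.20 ± 0.14, or 32.0-fold (adjusted p = 3.7e-09). SLC47A2, an organic cation exporter, fell 28.0-fold and TM4SF1, a tetraspanin-like surface protein, 14.7-fold. POPDC3 fell 6.77-fold, ACKR3, a chemokine scavenging receptor, 6.47-fold, TFPI, the inhibitor of tissue factor, 6.01-fold and the long non-coding RNA LNCAROD 5.88-fold. SPAG16 fell at least 5.69-fold, to a dim signal of 4.84 ± 0.44 (SD, n = 3), ABCA12, a lipid transporter, 5.60-fold, PADI3, a peptidylarginine deiminase, 5.38-fold, CR2, a complement receptor, 5.09-fold and SULF1, a heparan sulfate sulfatase, 5.00-fold. Adjusted p for the named rises and falls other than CD36 and TSPAN7 lay between 3.7e-09 and 2.2e-05, and the 3 arrays of one group lay apart from the 3 of the other for each.

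Across the array, 1614 genes were higher and 1077 lower in knockout than in control cells, 2691 of 33578 tested (8.01%, limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 379 were higher and 276 lower by at least 2-fold, 655 in all. The 2 groups did not overlap in 8482 genes (25.3%), where chance gives 10% for 3 arrays against 3. The count fell to 1668 without knockout replicate 2, to 1086 with an unmoderated test, to 1081 when tested against a fold change of 1.2 and to 1560 when all probe sets were tested. The higher genes numbered 1044 without knockout replicate 1 and 1008 without knockout replicate 2, and the lower genes 660 without knockout replicate 2. After repeated quantile normalization 1348 genes were higher and 1209 lower, so the excess of rises depended on the scaling of the arrays, and with array medians set equal 1698 were higher and 1023 lower.

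**Figure D1:**
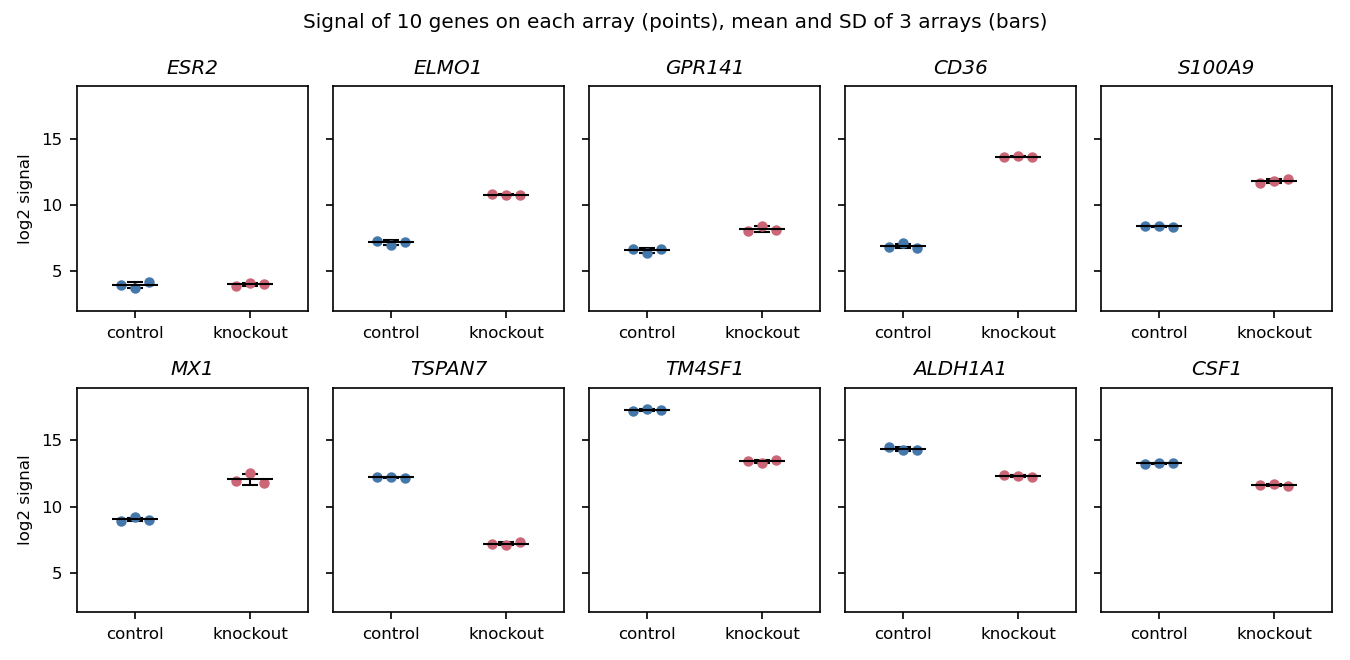
Log2 signal (vertical axes) of 10 genes on each control and knockout array (points), with the mean and SD of the 3 arrays (bars). ESR2 stays near 4 in both groups, CD36 goes from 6.91 to 13.66 and TSPAN7 from 12.20 to 7.20.

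ELMO1 and GPR141 were fixed for naming because the study's published work on these cells is known to concern them, so their change here is not independent evidence. ELMO1, an adaptor that activates the small GTPase RAC1 with DOCK proteins, rose from 7.17 ± 0.18 to 10.78 ± 0.05 (log2 signal, SD, n = 3), or 12.2-fold (SE of the log2 difference 0.13, adjusted p = 8.1e-08). GPR141, an orphan G protein-coupled receptor, rose from 6.57 ± 0.17 to 8.20 ± 0.23, or 3.08-fold (SE 0.15, adjusted p = 6.9e-05). Of 58 measured G protein-coupled receptors, 7 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.85). S1PR1, a sphingosine-1-phosphate receptor, rose at least 4.18-fold from a dim control signal of 4.51, and LPAR3, a lysophosphatidic acid receptor, rose 3.96-fold. Of 54 actin nucleation and lamellipodium genes, 6 rose and 4 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.81).

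Among interferon-stimulated genes, more rose than fell in knockout cells. Of 45 measured, 17 rose, 5 fell and 23 did not pass (21 and 6 adjusted over the list alone). MX1, an antiviral GTPase, rose 8.21-fold (adjusted p = 4.6e-06), OAS1, an RNA-sensing synthetase, 3.28-fold and GBP2, a guanylate-binding protein, 3.12-fold. SAMD9L fell 3.88-fold (adjusted p = 2.5e-05) and PARP14 1.85-fold. Camera's call (adjusted p = 8.8e-05) did not hold with an estimated correlation (adjusted p = 0.16). Antigen presentation genes that passed went the other way: of 26 measured, 0 rose, 7 fell and 19 did not pass (2 and 8 adjusted over the list alone). PSMB9, an immunoproteasome subunit, fell 3.60-fold (adjusted p = 8.7e-06), CTSS, a lysosomal protease, 3.21-fold and PSMB8 1.81-fold. With camera the shift had an adjusted p = 0.00059, and with an estimated correlation the call was lost (adjusted p = 0.22). Of 27 leukocyte markers, only CD68 passed, at 1.72-fold higher (adjusted p = 0.0043), and the median of that list was 0.02. Of 42 NF-kB target and inflammatory cytokine genes, 3 rose and 8 fell (3 and 11 adjusted over the list alone). CCL20, a chemokine, fell 4.31-fold, CSF1, the macrophage growth factor, 3.15-fold and IL1RN 2.83-fold, whereas SAA1 rose 3.58-fold and IL18 3.30-fold. In camera this list passed (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.16).

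Some mitosis genes rose and some replication-dependent histone genes fell. Of 50 mitosis genes, 14 rose, 2 fell and 34 did not pass (26 and 2 adjusted over the list alone). NDC80, a kinetochore protein, rose 1.95-fold, DLGAP5 1.86-fold and KIF2C, a kinesin, 1.85-fold, whereas CDK1 fell 1.49-fold. Camera's call (adjusted p = 2.6e-08) did not hold with an estimated correlation (adjusted p = 0.16). Of 28 histone genes, 0 rose, 9 fell and 19 did not pass (0 and 15 adjusted over the list alone). H2AC6 fell 1.94-fold, H2AC4 1.94-fold and H2BC4 1.87-fold, with adjusted p of 0.0012 to 0.0051. With camera the shift had an adjusted p = 9.3e-10, and with an estimated correlation the call was lost (adjusted p = 0.13). Histone genes are near-identical copies, so which copy a probe set measured is uncertain. Bright small nucleolar and small nuclear RNA genes, 123 by their RefSeq class, had a median log2 difference of -0.33. Of 49 DNA replication genes, 2 rose and 5 fell, also when adjusted over the list alone. RFC3, a clamp loader subunit, fell 2.00-fold, and E2F8 rose 1.57-fold. In camera this list passed (adjusted p = 0.048), but not with an estimated correlation (adjusted p = 0.46), with a replicate block (adjusted p = 0.063), on ranks or with the mean of all probe sets of a gene. It was also lost without control replicate 1, 2 or 3 or knockout replicate 2 or 3, with a highest adjusted p of 0.11.

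Some genes of lipid synthesis and of stress responses also passed. Of 21 cholesterol synthesis genes, 5 rose and 1 fell, also when adjusted over the list alone. TM7SF2, a sterol reductase, rose 4.63-fold (adjusted p = 4.1e-06), CYP51A1 1.84-fold and IDI1 1.57-fold, whereas SQLE, squalene epoxidase, fell 1.36-fold. Camera's call (adjusted p = 0.0022) did not hold with an estimated correlation (adjusted p = 0.16). Of 23 fatty acid synthesis genes, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.087). These were FADS2, a fatty acid desaturase (5.83-fold), SCD, stearoyl-CoA desaturase (2.30-fold), and SREBF1 (1.68-fold). Of 33 NRF2 and oxidative stress genes, 2 rose and 8 fell (4 and 13 adjusted over the list alone). ALDH3A1 fell 3.49-fold, ABCC4 3.10-fold and AKR1B10 2.55-fold, and HMOX1, heme oxygenase, rose 1.84-fold. With camera the shift had an adjusted p = 5.1e-05, and with an estimated correlation the call was lost (adjusted p = 0.46). Of 40 unfolded protein response genes, 5 rose and 2 fell (9 and 2 adjusted over the list alone). DNAJB9 rose 1.98-fold and XBP1, a transcription factor of this response, 1.86-fold, and SLC7A11, a cystine transporter, fell 1.79-fold. In camera this list passed (adjusted p = 0.016), but not with an estimated correlation (adjusted p = 0.46), after repeated quantile normalization or among genes above the median brightness.

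Several epithelial and growth factor genes differed. Of 29 luminal epithelial markers, 6 rose and 0 fell (7 and 2 adjusted over the list alone). CLDN3, a tight junction protein, rose 2.59-fold, KRT19, a keratin, 2.37-fold and GATA3, a luminal transcription factor, 2.30-fold. Camera's call (adjusted p = 0.042) did not hold with an estimated correlation (adjusted p = 0.46), after repeated quantile normalization, among genes above the median brightness or on ranks. It was also lost without control replicate 2 or 3 or knockout replicate 1, with a highest adjusted p of 0.084. Of 39 estrogen-responsive genes, 9 rose and 4 fell (11 and 4 adjusted over the list alone), with a camera adjusted p of 0.067. The list passed without knockout replicate 1 (adjusted p = 0.040) and without genes in the blocks (adjusted p = 0.020). SLC7A2 rose 4.67-fold and CA12, a carbonic anhydrase, 4.58-fold, whereas IGFBP5 fell 3.26-fold and PKIB 3.08-fold. Of 32 PI3K and FOXO genes, 11 rose and 4 fell (15 and 5 adjusted over the list alone). INSR, the insulin receptor, rose 3.41-fold, CCNG2, a FOXO target, 3.34-fold and AKT1 3.07-fold, whereas IGFBP2 fell 3.70-fold and IRS2 2.47-fold. With camera the shift had an adjusted p = 0.017, and with an estimated correlation (adjusted p = 0.19) or on ranks the call was lost. Of 43 ERBB and MAPK feedback genes, 5 rose and 8 fell (8 and 8 adjusted over the list alone). The ERBB ligands NRG4, NRG1 and BTC fell 4.34-fold, 4.32-fold and 2.50-fold, and the feedback inhibitors SPRY4 and DUSP4 rose 2.61-fold and 2.26-fold. That list's median was 0.05, whereas its mean was -0.02 and camera gave a downward direction (adjusted p = 0.92). Of 25 stem and progenitor genes, 5 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.43). KIT, a receptor tyrosine kinase, rose at least 6.60-fold from a dim control signal of 4.70, whereas ALDH1A1 fell 4.07-fold.

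**Figure D2:**
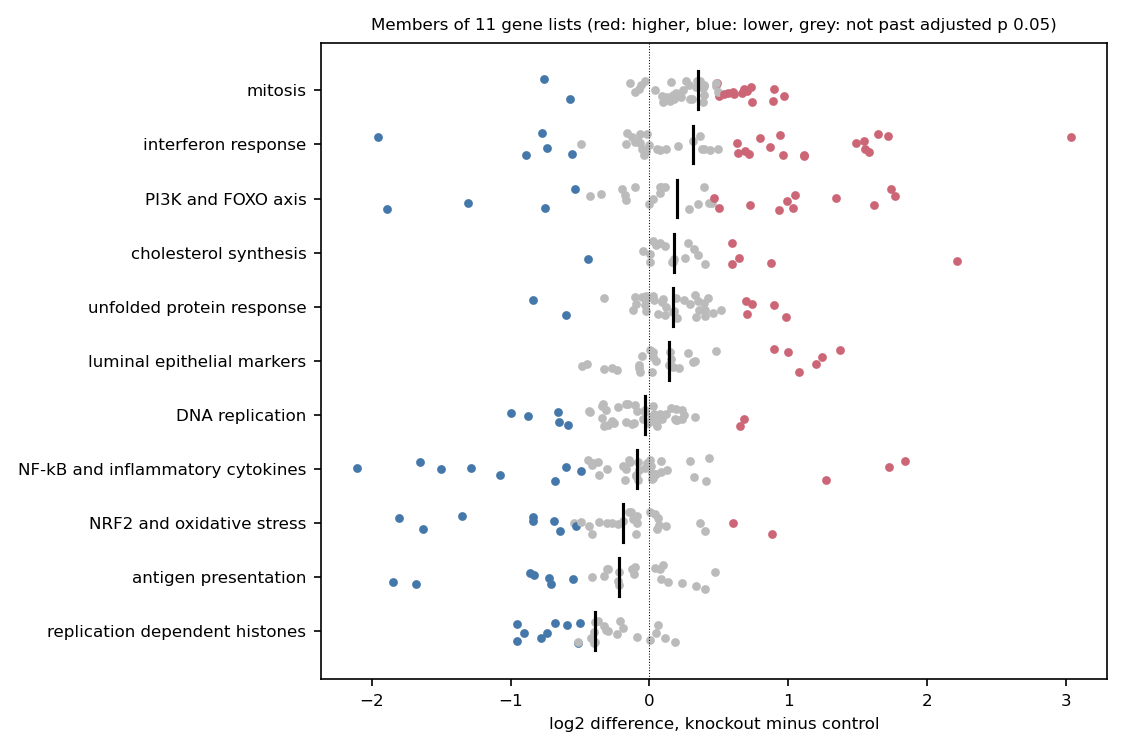
Log2 difference, knockout minus control (horizontal axis), of each measured member (points) of 11 of the 12 lists past camera's threshold, with the list median (bars). Medians run from -0.39 for histones to 0.35 for mitosis, and no call of these lists held with an estimated correlation.

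The lists of this paragraph did not pass camera in the main setting, with adjusted p of 0.060 to 0.99. Epithelial junction genes passed without knockout replicate 2 (adjusted p = 0.038) or 3 (adjusted p = 0.048) and with an intensity trend and robust moderation (adjusted p = 0.032). Fibroblast markers passed without control replicate 1 (adjusted p = 0.037) and without genes in the blocks (adjusted p = 0.030), and respiratory chain genes after repeated quantile normalization (adjusted p = 0.027). Of the cell type markers, 0 of 19 endothelial genes passed, 0 of 19 fibroblast genes rose and 2 fell, 1 of 20 basal genes rose and 2 fell, and of 14 adipocyte genes only CD36 passed (camera adjusted p of 0.12 to 0.85). Counts over all genes were 5 higher and 2 lower of 38 epithelial junction genes, 6 and 6 of 34 focal adhesion genes, 6 and 7 of 42 matrix protease genes, and 3 and 5 of 35 mesenchymal genes. They were 4 and 6 of 36 TGF-beta and BMP genes, 2 and 5 of 31 WNT and Hippo genes, 3 and 0 of 24 Notch genes, and 3 and 3 of 40 guidance genes. They were 4 and 3 of 37 nuclear receptor genes, 4 and 4 of 36 apoptosis genes, 2 and 1 of 31 p53 genes, 5 and 3 of 39 hypoxia and glycolysis genes, 3 and 4 of 39 respiratory chain genes, and 0 and 0 of 34 ribosomal protein genes. Adjusted over the list alone, the rises and falls were 5 and 3, 6 and 8, 8 and 7, and 4 and 5 for junction, adhesion, protease and mesenchymal genes. They were 7 and 6, 2 and 5, 3 and 0, and 5 and 3 for TGF-beta, WNT, Notch and guidance genes, and 7 and 4, 6 and 5, 2 and 2, 8 and 4, 3 and 4, and 0 and 0 for the last 6 lists. Among the markers they were 0 and 0 for endothelial, 0 and 2 for fibroblast, 1 and 2 for basal and 2 and 0 for adipocyte genes, and 1 and 0 for leukocyte genes. Of the mesenchymal genes, TGFB1 fell 3.09-fold, S100A4 2.27-fold and FN1, fibronectin, 2.08-fold, whereas TGFBI rose 2.29-fold. The signs of median, mean and camera direction were not all alike for the mesenchymal, matrix protease, basal, endothelial and Notch lists.

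Shifts shared by neighbouring genes were sought along the chromosomes. Among 11766 bright protein-coding genes placed in RefSeq order, 7 blocks of neighbouring genes shifted together. On chromosome 13, 153 genes from GTF3A to MCF2L had a median log2 difference of -0.80, and 104 of them were called lower. On chromosome 2, 217 genes from SESTD1 to MTERF4 had a median of -0.51. The medians were 0.65 over 59 genes from HTR3C to PAK2 on chromosome 3, and 0.77 over 18 genes from APC to FAM170A on chromosome 5. They were -0.35 over 48 genes from LRATD2 to CYC1 on chromosome 8, -0.49 over 22 genes from GPR65 to ITPK1 and 0.90 over 35 genes from EML1 to AKT1, both on chromosome 14. Blocks held 343 of the 2691 called genes (12.7%), 255 of the 1077 lower ones (23.7%) and 3.95% of tested genes. They were found from the same differences, so they hold more called genes by construction. Of the genes named above, ACKR3, TFPI, SPAG16, ABCA12, CCL20, IGFBP5, IGFBP2 and FN1 lay in the chromosome 2 block, RFC3, ABCC4 and IRS2 in the chromosome 13 block, and CATSPERB and AKT1 in the chromosome 14 blocks. CATSPERB rose although it lay in the falling block from GPR65 to ITPK1, and AKT1 lay in the rising one. Outside the blocks, 1526 genes were higher and 822 lower in the same fit. ESR2 lay in no block.

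**Figure D3:**
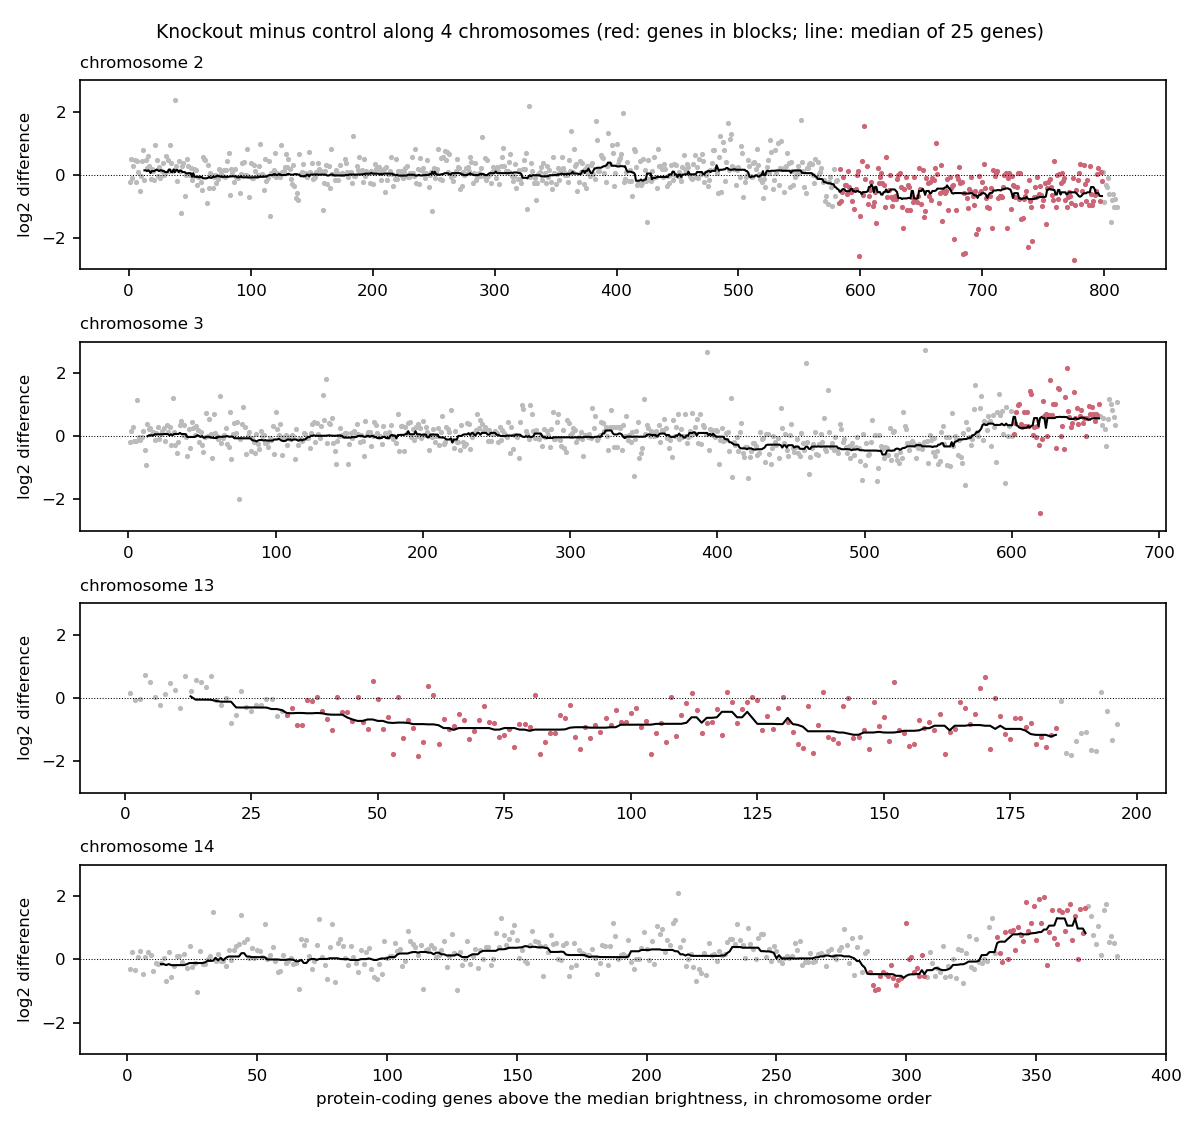
Log2 difference, knockout minus control (vertical axes), of bright protein-coding genes in chromosome order (horizontal axes) on chromosomes 2, 3, 13 and 14. Red points lie in blocks, the line is the median of 25 neighbouring genes minus that of all ordered genes (0.07), and 3 of 2058 genes lie outside the axis limit of 3. The chromosome 13 block, at a median of -0.80, spans most of the genes drawn there.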

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

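The tests of leukocytes, of fewer cells in S phase, of blocks found in every second gene, of the largest window of each block and of changed list members inside the blocks were chosen only after the results were seen.

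Probe sets without a single gene symbol take no part in the comparison of genes. In a limma fit of all 134748 probe sets, 201 of the 99220 such probe sets were higher and 184 lower in knockout cells, which is a signal in data not otherwise reported. The largest measured rise among these was at least 9.80-fold, from a dim control signal (TC1000011753.hg.1, log2 signal 4.09 ± 0.17 to 7.39 ± 0.46, SD, n = 3, adjusted p = 0.00011) and the largest fall 8.44-fold (TC1500007972.hg.1), both chosen after their values were seen.

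Neighbouring genes shifted together in 7 blocks. The largest block median of 1 array against the other 2 of its group was 0.144, beside 0.354 for the smallest block median. Because blocks were chosen for large medians between the groups, this pair alone does not decide on variation between arrays of 1 group. On chromosome 13, genes that took no part in the search lay at -0.957, and the block's largest value within a group was 0.062. That argues against such variation there. Chance order is argued against by the largest window of each block, at least 0.587 relative to all ordered genes, beside at most 0.476 anywhere in 1000 new random orders that set no threshold. Medians over whole blocks, the smallest 0.423 on chromosome 8, decide nothing here, since the blocks were chosen with a threshold of 0.465. With blocks sought in every second gene, 4 stretches were found, inside the chromosome 2 and 13 blocks and the rising chromosome 14 block. In the 4 stretches found, the genes in between, which took no part, were all shifted to the same side as their stretch. The shift was 0.804 where 200 random draws reached 0.746 in the closest case (4 genes on chromosome 2). On chromosome 13 the median was -0.957 against 0.123 (70 genes). A different number of copies of these segments in the 2 cell populations could not be decided. The 561 bright chromosome 13 probe sets not used to find blocks had a median of -0.066 (SE 0.015). That met the bound written beforehand against it, but the bound was judged too weak once the value was seen. In the fit of all probe sets, such probe sets were called in 1.53% of cases on other chromosomes, against 8.0% of bright coding genes. Of the 561, the 13 with several symbols had a median of -0.98 and the other 548 a median of -0.063. The first value would go with any shift of the genes in that region and does not single out copy number. DNA was not measured, so copy number and an effect of the knockout itself both stay open.

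Of 45 interferon-stimulated genes 17 rose and 5 fell (median 0.32), while of 26 antigen presentation genes 0 rose and 7 fell (median -0.22), and both list calls were lost with an estimated correlation (adjusted p = 0.16 and 0.22). Of the changed members, 0 of the 17 rises and 0 of the 7 falls lay inside the blocks of shifted chromosome segments. Their own position in a block therefore does not account for them. With 1 and 0 list members inside the blocks, this count could hardly have come out otherwise. Whether genes in the blocks acted on these genes was not tested. Medians without block members, 0.340 and -0.22, decide nothing, as this took out only 1 interferon gene and 0 antigen presentation genes. As a list, the leukocyte markers did not rise. Their median was 0.022 (27 genes, SE 0.050), beside 0.022 over all tested genes, and 1 of them passed. Only 10 of the 27 were bright, which limits what they show. The rule compared their median with the interferon median, whose own SE was 0.17. By that rule, leukocytes mixed into the knockout cultures could not be decided on. An effect of the knockout stays open as untested.

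Of 28 histone genes 0 rose and 9 fell (median -0.39), while of 50 mitosis genes 14 rose and 2 fell (median 0.35), and both list calls were lost with an estimated correlation (adjusted p = 0.13 and 0.16). Fewer cells in S phase stay open. The DNA replication list had a median of -0.036 beside a bound of -0.196. It lay above that bound by more than 2 SE of the difference (SE 0.063), which met the rule written against this explanation. The list's members went both ways, with an SD of 0.331, wider than that gap. A spread between members is not the uncertainty of a median, so it does not set the rule's result aside. Camera, however, called the list lower (adjusted p = 0.048), which goes with fewer cells in S phase. That call was lost with an estimated correlation (adjusted p = 0.46) and in several other settings. The values thus point both ways. A difference in the recovery of RNA without a poly(A) tail is consistent with the median of -0.333 (SE 0.027) of 123 bright small nucleolar and small nuclear RNA genes by RefSeq class. A first version that chose these genes by name gave 0.015 over 642 genes, which would have argued against this explanation, and was corrected after that was seen because it took in 476 RNU pseudogenes. A lower copy number of the histone clusters stays open, as 12 bright non-histone genes among them had a median of -0.057 (SE 0.198), and so does an untested effect of the knockout.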

How the results depend on the processing

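Leaving out genes inside the blocks was chosen after seeing the data; the other alternatives were planned. The count of 2691 changed genes ranged from 1668 to 2266 when 1 array was left out, higher genes from 1008 to 1378, lower genes from 660 to 925, and genes changed at least 2-fold from 655 to 717. Tested against a fold change of 1.2, 1081 genes passed (636 higher, 445 lower), with an unmoderated test 1086 (649 and 437), and over all probe sets 1560 (890 and 670). The first counts fewer genes by construction, and for the others the cause was not tested. Without genes in blocks, 2238 genes passed. Other settings gave 2303 to 3555. Higher and lower genes were 1348 and 1209 after repeated quantile normalization, beside 1614 and 1077. Lists past the threshold numbered 12 in the main setting, 9 to 12 when 1 array was left out, 10 after repeated quantile normalization, 9 among genes above the median brightness, 8 with camera on ranks, 0 with camera and an estimated correlation, and 19 and 37 with fry's directional and mixed tests, whose question differs. ESR2 ranged from -0.075 to 0.156 when 1 array was left out and turned negative without control replicate 2, and was below the brightness filter, so that setting gave no value. SYNE2 was -0.022 after repeated quantile normalization and ranged from -0.128 to 0.087 when 1 array was left out, and PGR from -0.036 to 0.218. None of these was ever past the threshold. Of 178 called named genes, 144 passed in every planned setting and 0 changed sign. With the replicate number as a replicate block, 2303 genes and 11 lists passed. The numbers do not pair the samples: same-numbered arrays' deviations correlated at -0.019, -0.010 and -0.030, and no array correlated best with its own number. Of the 10 splits of 6 arrays, the real one gave 2691 genes, 655 at least 2-fold and 12 lists, and the highest other gave 0, 0 and 2. With 10 splits no share can fall under 0.05, and 1 split was as large in each case. Signal over background is a limit for dim genes such as ESR2.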

Other observations

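The families in this part were chosen after the data were examined, so their tests are descriptive. Metallothionein genes, which bind zinc and copper, fell in 7 of 8 bright members, with a median log2 difference of -1.43 (adjusted p = 0.0094 with an estimated correlation). One of the 8, MT1L, is a transcribed pseudogene by its RefSeq class. MT2A fell from 15.11 ± 0.14 to 12.96 ± 0.09 (log2 signal, SD, n = 3), or 4.44-fold, and MT1X 4.01-fold. Of 12 bright MAGE genes, tumour antigens and their relatives, 6 rose and 0 fell (adjusted p = 0.018 with an estimated correlation), MAGEA1 by 6.73-fold. Of 9 interferon-induced transmembrane and guanylate-binding genes 7 rose (adjusted p = 0.011 with an estimated correlation), and of 5 immunoproteasome and peptide transporter genes 3 fell (adjusted p = 0.020 with an estimated correlation). Most members of the latter pair of families also belong to the interferon and antigen presentation lists. After repeated quantile normalization the metallothionein and MAGE medians were -1.48 and 0.45. Members of these families resemble one another, so which copy a probe set measured is uncertain. Of 12 S100 genes, 3 rose and 4 fell, S100A8 by 4.94-fold upward, and of 18 keratin genes 1 rose and 2 fell.

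ELMO1 and GPR141 are neighbours on chromosome 7. NME8, the next gene beyond GPR141, was also higher, 1.68-fold (log2 difference 0.75, SE 0.20, limma adjusted p = 0.044), whereas AOAH on the other side of ELMO1 differed by -0.20 (adjusted p = 0.41) and SFRP4, beyond NME8, by -0.22 (adjusted p = 0.49). Neighbours of ESR2 on chromosome 14 were chosen afterwards too. WDR89 was higher 2.22-fold (adjusted p = 0.00093), SGPP1 1.66-fold (adjusted p = 0.0070), ZBTB1 1.54-fold (adjusted p = 0.013) and PPP2R5E 1.35-fold (adjusted p = 0.04997), whereas SYNE2 and MTHFD1, on either side of ESR2, differed by 0.01 and 0.14 (adjusted p = 0.98 and 0.61). Of the 12 nearest coding neighbours measured, 4 were higher and 8 did not pass.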
